A study of Homo sapiens with 6 samples.

How the data were processed

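RNA was measured by sequencing in 6 libraries of LNCaP cells, 1 from untreated cells at 0 h and 1 each after 3, 6, 12, 24 and 48 h with 10 nM DHT. Groups and times came from the sample labels, and each column of the deposited table was tied to a sample by the time in its header. Per the labels' protocols, total RNA was extracted and libraries were made and sequenced for the Illumina GAIIx after growth of the cells in hormone-depleted serum. Genome build hg19 is named in the submitters' processing notes; the aligner, the counting tool, their versions and the use of strand are not given in the sources used here.

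The deposited table held 2 columns per library and 1 line per RefSeq transcript. The count column, per the file headers, held tags, and its values were whole numbers with a different sum in each library. The RPM column, which the file headers call ppm, held the same counts as scaled by the authors to the reads of the library; the count divided by the RPM was 1 constant per library, above the sum of its counts, and the listed transcripts held 86.9 to 89.5% of it. The analysis used the counts, and the deposited denominator was an alternative. Of 18051 lines 50 exact repeats were removed, which left 18001 transcripts, and counts of transcripts with 1 symbol were added, giving 17990 genes. Of 679 transcripts without a symbol 69 were resolved through a RefSeq table on GRCh38.p14, in which 16803 transcripts (93.3%) were found, and the other 610 were kept without a name. That table also gave the chromosome of 97.5% of the filtered genes. GC content and exon numbers came from GENCODE v29 transcripts on GRCh38, for 11140 (93.5%) of the filtered genes. No coordinates are printed, because the builds differ.

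Totals over listed transcripts were 13179917, 14113170, 13410529, 13627453, 20587956 and 15046808 counts in the order of time, 15079 to 15589 genes had at least 1 read, and the 10 most abundant genes took 5.01 to 7.39% of the counts. A count of 0 allows up to 3 counts, or 0.146 to 0.228 CPM. Intervals of single values are exact Poisson intervals and those of ratios exact conditional binomial intervals, at 95%. No molecular identifiers are named in the sources used here, so intervals and floors cover counting error only.

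Counts were scaled to CPM, the same total per library, over the listed transcripts, and changes were taken as log2((CPM + 1) of a DHT library over (CPM + 1) at 0 h), which understates the change of low genes. The 11916 genes with a mean of at least 20 counts over the 6 libraries entered. With 1 library per group there was no test across samples, and a change of at least 2-fold was a fixed rule of size. Sustained genes were past 2-fold in 1 direction at 12, 24 and 48 h, early transient genes past 2-fold at 3 or 6 h and within 1.5-fold at 24 and 48 h, and late genes past 2-fold at 24 and 48 h and within 1.5-fold at 3 and 6 h. All comparisons share the 0 h library, and 20 draws without change were simulated from it, with counting error only. The error was drawn for the DHT libraries, and the 0 h counts were kept as observed. The median change of each gene list was placed among 10000 random lists of the same size and makeup over 20 bins of mean expression, called at a percentile of at least 97.5 or at most 2.5 and described only for lists of at least 5 measured genes; a second draw also matched GC content, in 10 bins of GC content by 5 of expression. The order of the libraries was examined by enumerating all 360 orders, an order and its mirror being 1. Genes of 1 library at least 2-fold above or below all others were counted. The GC trend was removed by subtracting a lowess curve (span 0.3) of the change on GC content.

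The comparisons, the 2-fold rule, the count minimum, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The lists covered androgen-repressed genes, cholesterol synthesis and uptake, fatty acid synthesis, mitosis, DNA replication and G1/S, endoplasmic reticulum stress and secretion, glycolysis, polyamine synthesis, amino acid transport, immediate early genes, interferon response, neuroendocrine markers, p53 targets and apoptosis, DNA methylation and TET enzymes, splicing and paraspeckle proteins, prostate long non-coding RNAs, housekeeping genes, cytosolic ribosomal proteins, replication-dependent histones, oxidative phosphorylation, and markers of fibroblasts, leukocytes and basal epithelium. Some genes are on more than 1 list, such as MYC, ACSL3, CDC6, UBE2C and UHRF1. The rule named, at each time, the 10 genes with the largest increase and the 10 with the largest decrease (15 each at 24 h), the 10 sustained, 5 early transient and 10 late genes per direction, up to 4 members per list with the largest change at 24 h, and KLK2, KLK3, TMPRSS2 and FKBP5. Some genes and lists of the plan are not reported here. Genes outside the rule are said to be chosen after their values were seen, or stand as members of a list or of a count. Left unnamed were HEPN1, which overlaps HEPACAM on the other strand, 1 early transient transcript without a name and the long non-coding RNA, also among the 10 largest decreases at 12 h. Symbols are those of the deposited table, with a current symbol where it differs.

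Alternatives were pseudocounts of 0.5 and 2, no count minimum, a mean of at least 100 counts, scaling by the median of ratios or the upper quartile, the mean of a list in place of its median, and an absolute Spearman correlation of at least 0.9 with the order. Those chosen after seeing the data were the GC correction, leaving out chromosome 4 and distal chromosome 15 along with genes of unknown chromosome, both together, the deposited denominator, thinning to the smallest library, the 3 h library as reference, leaving out libraries and GC-matched random lists. The code was tested on simulated data first, which held counting error but no spread between cultures or libraries. The rates below therefore test the code and are not error rates of the calls in the real libraries. For 24 h against 0 h over 11996 genes it called 0 of 49 genes planted at 1.5-fold, 46 of 48 at 3-fold, 50 of 50 at 4-fold, 46 of 48 at 8-fold and 1 of 11801 unchanged genes. For 6 h against 0 h with a planted GC trend over 11234 genes, 232 of 11134 unchanged genes were called without correction and 0 with it, and 99 of 100 genes planted at 4-fold. Of genes planted as sustained and late, over 11990 genes, 60 of 60 and 58 of 60 were recovered. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.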

Results

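The series followed messenger RNA levels in LNCaP cells, a human prostate cancer line that grows in response to androgens, while the cells were exposed to dihydrotestosterone (DHT), a potent natural androgen. Per the labels' protocols, the cells were first kept in hormone-depleted serum, and total RNA was then sequenced on an Illumina GAIIx. The question named by the series is which transcripts are regulated by androgen and when. There were 6 libraries, 1 per group: 1 from untreated cells (0 h) and 1 each after 3, 6, 12, 24 and 48 h with 10 nM DHT. The libraries held 13179917, 14113170, 13410529, 13627453, 20587956 and 15046808 counts over the listed transcripts in the order of time. No group had a second library, so no difference was set against a spread between replicates and no p-value was given. A gene was called higher or lower when it differed by at least 2-fold from the 0 h library on the log2(CPM + 1) scale, where CPM is the count scaled to the same total in every library, and 11916 genes had the mean count of at least 20 that this required. Intervals of 95% given with fold values cover counting error only. Libraries of untreated cells taken after 0 h were not used here.

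After 24 h with DHT, the comparison described most fully here, STEAP4, a metalloreductase of the cell membrane, went from 1.44 to 319 CPM, a ratio of 221 (95% interval 142 to 368). FKBP5, a co-chaperone of steroid receptors, rose 38.7-fold (36.1 to 41.6) from 59.0 to 2286 CPM, and TMPRSS2, a serine protease of prostate epithelium, rose 11.1-fold (10.8 to 11.4) to 4479 CPM. KLK3, which encodes prostate-specific antigen, was already at 4727 CPM in untreated cells and rose 2.12-fold (2.10 to 2.14), while its paralog KLK2 rose 2.97-fold (2.91 to 3.04).

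The 15 genes with the largest increase at 24 h were, besides STEAP4 and FKBP5, led by NCAPD3, a subunit of condensin II, with a log2 change of 5.63 and 3982 CPM. ERRFI1, a feedback inhibitor of the epidermal growth factor receptor, had 4.60, and the transcription factors TBX15 and MAF had 4.49 and 4.48. RHOU, a small GTPase, reached 4.42 and the acyl-CoA synthetase ACSL3 4.38. CSGALNACT1, an enzyme of chondroitin sulfate synthesis, reached 4.205, LIFR, the receptor of leukemia inhibitory factor, 4.16, the elongation factor partner EAF2 4.12 and the centromere protein CENPN 4.12. TMCC3, the co-chaperone DNAJB9 and the kinase SGK1 completed the set at 4.02, 3.99 and 3.93; SGK1 was low throughout, at 0.228 CPM before treatment and 17.7 CPM at 24 h.

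Among the genes that fell by 24 h, DDC, which encodes DOPA decarboxylase, went from 131 to 5.003 CPM, 0.0383 times its level at 0 h (0.0311 to 0.0467). CXCR7 (now ACKR3), an atypical chemokine receptor, went from 522 to 29.9 CPM, 0.0573 times its earlier level (0.0527 to 0.0623). The transglutaminase TGM3 had a log2 change of -4.23, the receptor of glucagon-like peptide GLP1R -3.85 and the adhesion molecule HEPACAM -3.65. LRRN1, SLITRK3 and CBLN2, known for their part in neuronal contacts, had -3.50, -3.25 and -3.12 from levels of 168, 268 and 319 CPM. ABCA1, the cholesterol exporter, had -3.15, C1QL4 -3.13, VWA2 -3.32 and IL1RN, the antagonist of the interleukin-1 receptor, -3.06. The deiodinase gene DIO3 and the lipocalin gene LCN2 also fell at 24 h, with -3.28 and -3.21, but were at 0.75 and 0.58 at 48 h.

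In all, 1249 genes were at least 2-fold higher and 1287 at least 2-fold lower at 24 h than at 0 h. These changes depended on the GC content of the transcripts: across genes, the change at 24 h correlated with GC content at r = -0.515, and genes are not independent replicates. Among the 11140 genes with a GC value, 1165 were higher and 1203 lower, and with that trend removed 790 and 734. Each of the genes at the top of either direction that had a GC value, 14 higher and 14 lower, stayed past 2-fold. This followed from their choice by size. Median log2 changes at 24 h ran only from 0.79 in the genes with the lowest GC content to -0.66 in those with the highest. It therefore says nothing of genes with smaller changes.

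**Figure D1:**
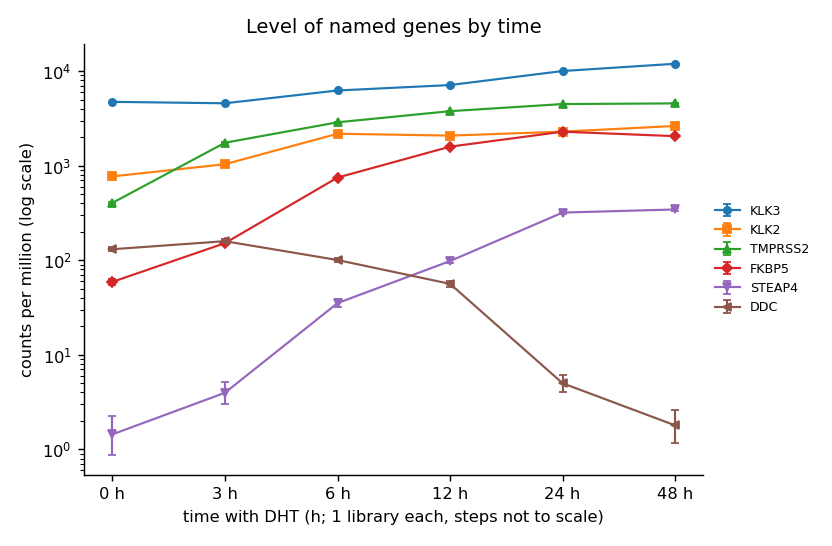
CPM (log scale) of 6 named genes in the 6 libraries, plotted against the time with DHT in h, 1 library per point; bars are 95% Poisson intervals of the count. FKBP5 and STEAP4 climbed from 59.0 and 1.44 to 2286 and 319 CPM by 24 h, while DDC went from 131 to 1.79 CPM by 48 h.

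Lipid synthesis genes were higher at 24 h. Of 21 measured genes of cholesterol synthesis and uptake, 11 rose and 0 fell, with a median log2 change of 1.06 that lay at percentile 100 of 10000 random lists of like expression (GC-corrected median 1.12). The cholesterol carrier STARD4 had 2.76, HMG-CoA synthase HMGCS1 2.71, the sterol sensor partner INSIG1 2.69 and the isomerase IDI1 2.67. For fatty acid synthesis, 9 of 13 genes rose and 0 fell at 24 h (median 1.24, percentile 100, corrected 1.12), with ACSL3 at 4.38, the elongases ELOVL7 and ELOVL5 at 3.45 and 1.66, and the desaturase FADS2 at 1.70. By 48 h the counts were 12 of 21 and 10 of 13, and the medians 1.2 and 1.99. At 3 h, 1 of the cholesterol genes and 0 of the fatty acid genes had risen.

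Genes of the secretory pathway and of small-molecule supply were also higher at 24 h. On the list of endoplasmic reticulum stress and secretion, 9 of 21 genes rose and 0 fell at 24 h (median 0.95, percentile 100, corrected 1.10), among them DNAJB9 with 3.99, DNAJC3 with 2.52 and ERN1, the stress sensor kinase, with 2.10. SEC24D, a coat protein of transport vesicles, had 3.20. In polyamine synthesis, 4 of 8 genes rose (median 0.99, percentile 99.8, corrected 0.83): ODC1, the first enzyme of the pathway, went from 521 to 4585 CPM, SMS had 2.64, AMD1 1.79 and SAT1, which acts in polyamine breakdown, 2.44. Of 11 amino acid transporters 7 rose and 0 fell (median 1.47, percentile 100, corrected 1.53), with SLC38A4 at 3.73, the cystine transporter SLC7A11 at 3.31, SLC38A2 at 2.23 and SLC1A4 at 1.89. Of 9 replication-dependent histone genes, which have close copies, 1 rose at 24 h and 3 at 48 h, with medians of 0.69 and 0.98 (percentiles 98.4 and 99.1, corrected 0.97 and 1.09); after correction 4 and 6 were higher by 2-fold. HIST2H2BE had 1.31, HIST1H2BD 0.83, HIST1H2BC 0.74 and HIST1H1E 0.71 at 24 h.

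Cell division genes were lower at 24 h. Of 21 mitosis genes, 12 fell and 0 rose, with a median of -1.12 (percentile 0, corrected -1.24, with 17 genes lower after correction). PLK1, a kinase of mitotic entry, went from 41.7 to 9.03 CPM, and CDC20, KIF20A and BIRC5 had -2.00, -1.74 and -1.70. For DNA replication and G1/S, 4 of 23 genes fell and 1 rose (median -0.56, percentile 0.290, corrected -0.43). The replication licensing gene MCM2 had -1.20, CCNE1 -1.08 and CDT1 -1.05, while CDC6 had 1.23. After GC correction MCM2, CDT1 and MCM3, the fourth gene that fell, stood at -0.73, -0.39 and -0.83, short of 2-fold, and CCNE1 had no GC value; 1 other gene of the list, GINS1, was then lower by that size (-1.09, and -0.65 before). CCNE1 and CDT1 no longer reached 2-fold when libraries were scaled by the median of ratios.

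Genes known as repressed by androgen were also lower at 24 h: 7 of 13 fell and 2 rose, with a median of -1.15 (percentile 0, corrected -1.17). DDC and CXCR7 were among them, as were OPRK1, the kappa opioid receptor, with -2.82 from 8.80 CPM, and MYC with -2.58 from 398 CPM. Of single genes named by the fixed rule, IGF1R, the receptor of insulin-like growth factor, had 2.89, TRIM36 2.48, ARFGAP3 2.08 and PIAS1 1.64. IGF1R, PIAS1, SEC24D and SLC7A11 lie in the chromosome regions described with the 12 h library, and their values at 12 h were -0.91, -1.53, 0.31 and -2.51. For glycolysis, 5 of 16 genes fell and 1 rose (median -0.68, percentile 0.0400, corrected -0.29, with 1 gene lower after correction). PFKM, PFKP and PKM2 (now PKM) had -1.41, -1.18 and -1.13; after GC correction PFKP, PKM2 and ENO1, which also fell, stood at -0.72, -0.71 and -0.62, and GPI, the fifth, had no GC value. PKM2 lies on distal chromosome 15 and was at -3.96 at 12 h. PFKFB2, which makes an activator of glycolysis, had 2.15.

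**Figure D2:**
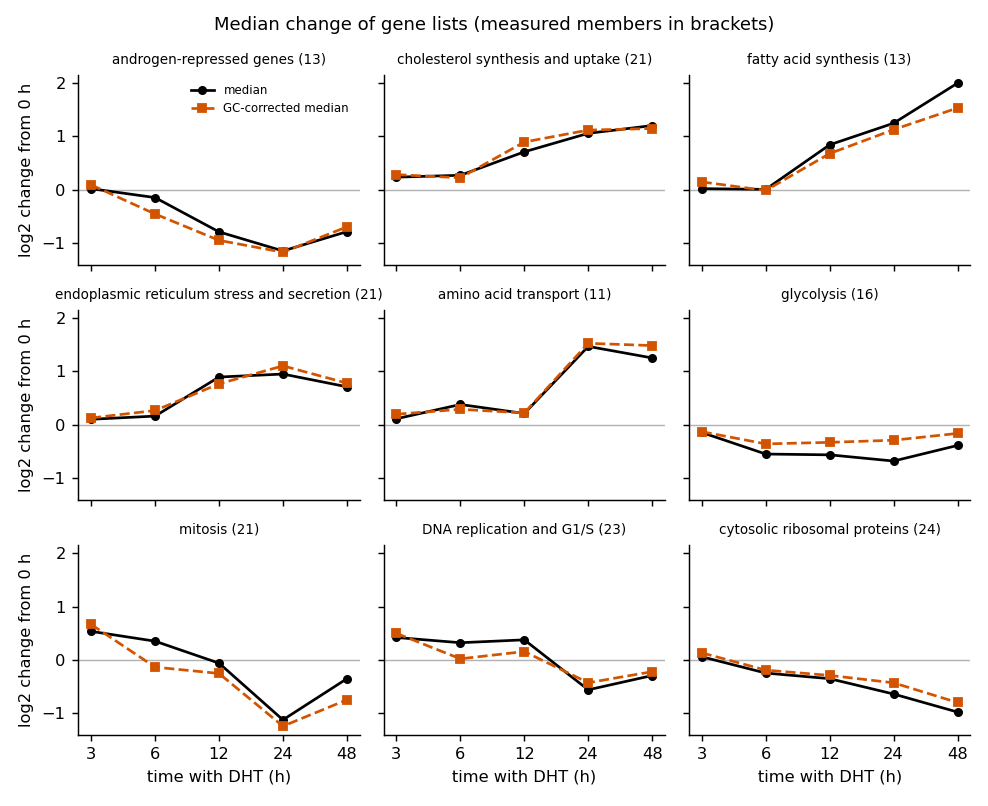
Median log2 change from 0 h of 9 fixed gene lists against the time with DHT (h), as measured (black) and after correction for GC content (orange dashed); measured members are in brackets. Fatty acid synthesis genes reached a median of 1.24 at 24 h, where mitosis genes were at -1.12.

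At 3 h few genes had moved: 89 were at least 2-fold higher and 103 lower. TMPRSS2 rose 4.32-fold (4.197 to 4.45), while KLK3 stood at 4566 CPM, a log2 change of -0.05, and KLK2 at 0.43. ID3, an inhibitor of helix-loop-helix transcription factors, had the largest increase, 3.29 from 0.910 CPM, ahead of TBX15 with 2.74, SGK1 with 2.69 and ID1 with 2.21 from 0.531 CPM; ID3 and ID1 are on the list of androgen-repressed genes. CYP1A1, an enzyme induced through the aryl hydrocarbon receptor, had 2.18 (and -0.49 at 12 h, on distal chromosome 15), TMCC3 2.14, MAF 2.13, SNAI2 2.06 and RHOU 1.98. SCNN1G, a subunit of the epithelial sodium channel, fell the most, from 17.8 to 1.56 CPM (-2.88). It was followed by BHLHB2 (now BHLHE40) with -2.28, PFKFB4 with -1.94, ZIC5 with -1.76, PPFIA4 with -1.72, the histone demethylase gene JMJD1A (now KDM3A) with -1.71, the collagen-modifying enzyme PLOD2 with -1.57, FOXN2 with -1.53, CNKSR3 with -1.52 and AKAP12 with -1.51. AKAP12 then rose to 113 CPM at 48 h from 7.89 CPM at 0 h.

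Cell division genes lay slightly above their 0 h level at 3 h, with medians of 0.53 for mitosis and 0.42 for DNA replication and G1/S, both at percentile 100, although 0 of 21 and 1 of 23 genes rose by 2-fold (CDC6, 1.02). Smaller shifts of whole lists at 3 h were a median of 0.23 for cholesterol genes (percentile 100), 0.23 for polyamine genes (99.5), 0.23 for histone genes (99.7), 0.17 for oxidative phosphorylation (99.9), 0.14 for interferon response (98.5) and -0.14 for glycolysis (0.470). The 12 measured immediate early genes had a median of 0.15 (percentile 99.2) and a mean of -0.09, of opposite sign. Their percentile was 97.3 among random lists matched on GC content as well, short of the 97.5 required, and the list held FOS at -1.43 and MYC at -1.28. GC-corrected, 105 genes were higher and 48 lower at 3 h, 68.6% higher among the changed genes against 47.2% (84 and 94) for the same genes without correction.

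At 6 h CCDC141 had the largest change, 4.14, from 1 count to 18.0 CPM. STEAP4 followed with 3.89, SGK1 with 3.72, FKBP5 with 3.64, EAF2 with 3.52, LIFR with 3.42, TBX15 with 3.41, RHOU with 3.29, the cold-sensing channel TRPM8 with 3.26 and the nicotinic receptor subunit CHRNA2 with 3.21. KLK2 had reached 2175 CPM (1.496) and KLK3 6232 CPM (0.40). SCNN1G was still the most reduced gene, with -2.83, ahead of the potassium channel KCNK5 with -2.12, FOS with -1.93, CXCR7 with -1.92, DCHS1 with -1.84, C1QL4 with -1.83, PCTK3 (now CDK18) with -1.82, CNKSR3 with -1.82, NRXN2 with -1.82 and ZNF703 with -1.80. Polyamine genes had a median of 0.74 (percentile 99.8, corrected 0.21). Glycolysis lay at -0.55 (percentile 0.0300, corrected -0.36).

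The 6 h library held 1826 genes at least 2-fold above 0 h and 359 below, 83.6% of the changed genes being higher. Its changes followed GC content closely (r = -0.739 across genes). The 1114 genes with the lowest GC content, 37.4% at the median, had a median log2 change of 1.16, and the 1114 with the highest, 64.6%, had -0.60. Of the genes with a GC value, 1701 were higher and 341 lower, and with the trend removed 423 and 174, 70.9% higher among those changed. At 3 h the correlation was 0.231, of the opposite sign, and at 12 and 48 h it was -0.430 and -0.558.

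**Figure D3:**
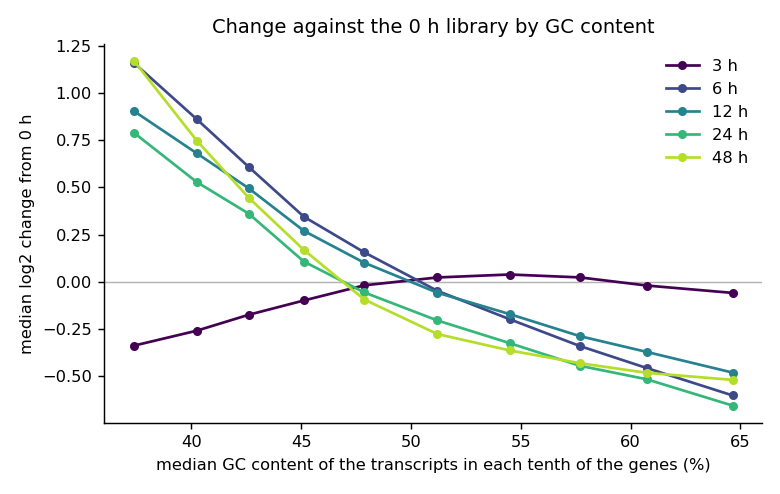
Median log2 change from 0 h against the median GC content (%) of the transcripts in 10 groups of equal size of the 11140 genes, 1 line per time with DHT. From 6 h on the lines fall with GC content, at 6 h from 1.16 to -0.60. The 3 h line rises from -0.34 to 0.04 and then falls to -0.06.

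At 12 h STEAP4 had 5.34, FKBP5 4.73, NCAPD3 4.66, EAF2 3.93, RHOU 3.88, SGK1 3.76, MAF 3.69, NNMT 3.61, ACSL3 3.603 and SLC16A6 3.57, the 10 largest increases. The 10 largest decreases all lay on chromosome 4 or on the distal part of chromosome 15. IMP3, on chromosome 15, went from 1234 counts at 0 h to 0 at 12 h, which allows a level of up to 0.220 CPM, and was back at 112 CPM at 24 h. MRFAP1, on chromosome 4, went from 319.7 to 3.08 and back to 443 CPM, and ZNF718 and ZNF595, also on chromosome 4, had 0 and 0 counts. TMEM129, C15orf39, MAML3, SLC26A1 and SNX33 had log2 changes of -5.71, -5.57, -5.56, -5.52 and -5.51.

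Distal chromosome 15 here means the part from LCTL to the end of the long arm, by gene order in a RefSeq table on GRCh38.p14, a boundary set after the data were examined. Relative to the mean of the 6 h and 24 h libraries, the median level left at 12 h was 10.4% over 389 genes of chromosome 4 and 8.04% over 165 genes of distal chromosome 15, against medians of 98.3 to 108.3% on the other chromosomes. In the 12 h library 473 genes were at least 2-fold below all 5 other libraries, 309 of them on chromosome 4, 151 on distal chromosome 15, 12 without a known chromosome and 1 elsewhere (SLC7A5, an amino acid transporter). The libraries at 0, 3, 6, 24 and 48 h had 67, 45, 14, 14 and 36 genes at least 2-fold above or below all others. Among genes of known chromosome outside both regions the largest decreases at 12 h were in SCNN1G (-2.89), CXCR7 (-2.88), OPRK1 (-2.56), the olfactory receptor gene OR51E1 (-2.54), DIO3 (-2.53), PLD1 (-2.52), EDN2 (-2.33), TGM3 (-2.32), TINAGL1 (-2.30) and SLC7A5 (-2.29).

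Over all chromosomes 1315 genes were higher and 952 lower at 12 h, 58.0% of the changed genes being higher. Without the regions and the genes of unknown chromosome there were 1288 and 427 (75.1% higher). Of the genes with a GC value, 1230 and 896 changed (57.9%), with GC correction 442 and 830 (34.7%), and with both settings 442 and 313 (58.5%). Lists with a high median at 12 h were cholesterol (0.71, percentile 99.96), fatty acid synthesis (0.84, 99.9), secretion (0.89, 100) and polyamine synthesis (1.03, 99.9), with corrected medians of 0.89, 0.68, 0.77 and 0.53. Low medians were found for androgen-repressed genes (-0.79, 0), glycolysis (-0.56, 0) and ribosomal proteins (-0.35, 1.26), with corrected medians of -0.95, -0.33 and -0.29. Splicing and paraspeckle genes had a median of 0.34 at percentile 97.6, which was 89.8 among random lists also matched on GC content.

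**Figure D4:**
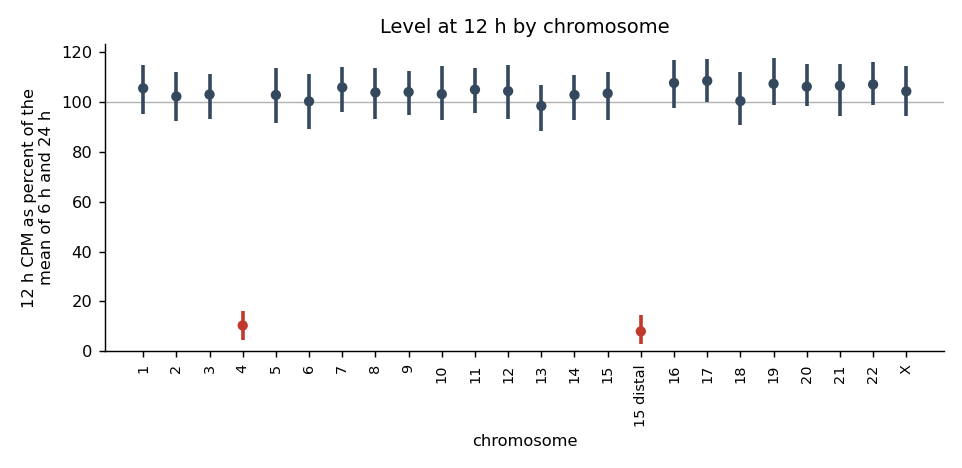
Level of genes in the 12 h library as a percent of the mean of the 6 h and 24 h libraries, by chromosome; points are medians over genes, bars span the quartiles. Chromosome 4 (10.4%) and distal chromosome 15 (8.04%) lie far below the other chromosomes, whose medians are 98.3 to 108.3%.

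At 48 h STEAP4 had 7.14, FKBP5 5.09, MAF 5.01, NCAPD3 4.99, ACSL3 4.80, LIFR 4.45, CENPN 4.21, the myosin-binding protein gene MYBPC1 4.196, RHOU 4.19 and the acute-phase glycoprotein gene ORM1, which has a close copy, 4.08. KLK3 reached 11949.9 CPM. DDC was down to 1.79 CPM (-5.56), followed by CBLN2 with -4.57, SLITRK3 with -4.29, TGM3 with -4.24, PLA2G2A with -3.95, GLP1R with -3.81, CAMK2N1, an inhibitor of a calmodulin-dependent kinase, with -3.71, HEPACAM with -3.59, LRRN1 with -3.57 and sucrase-isomaltase SI with -3.41. Fatty acid synthase FASN went from 2368 CPM at 0 h to 5609.9 at 24 h and 15476 at 48 h. The elongation factor gene EEF2 went from 18198 to 7903 and 7009.9 CPM, log2 changes of -1.20 and -1.38 that were -0.69 and -0.91 after GC correction, short of 2-fold. FASN and EEF2 were picked for their abundance after their values were seen. Of 24 cytosolic ribosomal protein genes, 11 fell and 0 rose at 48 h, with a median of -0.98 (percentile 0, corrected -0.80 with 5 lower, 3 of them among the 11). RPS3 had -1.35, RPL18 -1.26, RPS19 -1.23 and RPL8 -1.17; at 24 h the list median was -0.64 (percentile 0.1, corrected -0.43) with 0 genes past 2-fold.

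Lists with high medians at 24 h also had them at 48 h: secretion genes 0.71 (percentile 99.96), polyamine genes 1.18 (99.9) and amino acid transporters 1.252 (99.98), with corrected medians of 0.78, 0.61 and 1.48. Androgen-repressed genes were at -0.79 (percentile 0.190, corrected -0.70), with 5 of 13 lower. Mitosis genes had a median of -0.35 at percentile 3.27, short of the lowest 2.5%, but at 0.170 among random lists also matched on GC content (corrected median -0.75). Glycolysis was at -0.39, at percentiles 18.3 and 24.8 (corrected -0.16). In all 1791 genes were higher and 874 lower at 48 h; of the genes with a GC value 1687 and 817, and 797 and 537 after correction. The 24 h and 48 h libraries differed from each other at 204 genes (182 higher and 22 lower at 48 h).

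**Figure D5:**
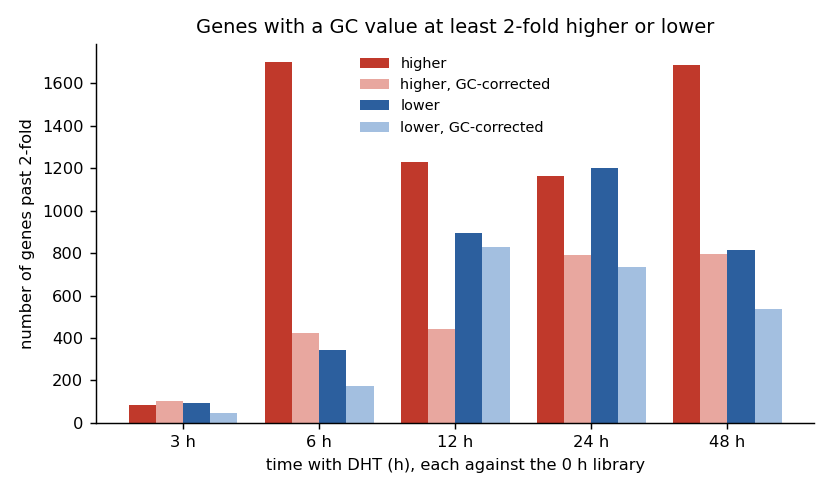
Number of genes at least 2-fold higher (red) or lower (blue) than in the 0 h library at each time with DHT (h), among the 11140 genes with a GC value, before (dark) and after (light) correction for GC content. At 6 h 1701 genes were higher before and 423 after correction; at 24 h 1203 and 734 were lower.

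By course, 893 genes were at least 2-fold higher and 337 lower at all of 12, 24 and 48 h. Ranked by their smallest change, the sustained increases were led by STEAP4, FKBP5, NCAPD3, RHOU, MAF, ACSL3, EAF2, NNMT, CENPN and ERRFI1. NNMT, which methylates nicotinamide, had 3.86 at 24 h. The sustained decreases among genes of known chromosome outside the regions lost at 12 h were led by CXCR7, OPRK1, PLD1 (-2.95 at 24 h), TGM3, HEPACAM, OR51E1, CNKSR3 and GRB10, an adaptor of insulin receptor signalling that went from 1048 to 146 CPM; KCNK5 was next. UGT2B17, which inactivates androgens by glucuronidation, also qualified (-2.44 at 24 h and -3.55 at 12 h), but it lies on chromosome 4 and has close paralogs. Counts drawn from the 0 h library with counting error only gave 0 sustained genes in each of 20 simulated draws, which hold no spread between cultures or libraries and no GC trend. The 0 h counts themselves were kept as observed in these draws. They therefore cannot show how many genes an error in that shared library would give. By their sizes, 3 independent lists would share 20.7 higher and 7.54 lower genes. Part of the excess over these can come from the single 0 h library that all comparisons share. Of the genes with a GC value 835 higher and 316 lower were sustained, and after correction 328 and 209, of which 274 and 128 were the same genes as before correction. Asked at 24 and 48 h only, without the 12 h library, 685 genes were lower and the number higher stayed within 1.5 times; against the 3 h library in place of 0 h, 1462 were higher and 198 lower.

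Early transient changes, at least 2-fold at 3 or 6 h and within 1.5-fold of 0 h at both 24 and 48 h, were seen for 120 genes upward and 43 downward. ID1 led the upward group, with 2.21 at 3 h and 0.29 at 24 h, followed by DNAH8 (2.16 at 6 h), IGFBP3, a binding protein of insulin-like growth factors (1.79), ICA1L (1.77) and FAT2 (1.69). Downward, JMJD1A had -1.71 at 3 h and 0.40 at 6 h, NOTCH3 -1.38 at 6 h, RAP1GAP -1.33 at 6 h and the mitophagy gene BNIP3 -1.29 at 3 h. Late changes, at least 2-fold at both 24 and 48 h and within 1.5-fold at 3 and 6 h, were found for 63 genes upward and 203 downward. Upward these included GNMT, which methylates glycine (3.26 at 48 h), the growth factor PTN (2.76), C1orf113 (now SH3D21, 2.58), the desaturase SCD (2.41), sorbitol dehydrogenase SORD (2.07), CREB3L4 (1.32) and MMRN2 (2.17). UGT2B11 (3.02) and the sterol oxidase SC4MOL, now MSMO1 (2.18), were also late; they lie on chromosome 4, with -0.81 and -1.19 at 12 h, and at 24 h had 0.58 and 0.93 after GC correction. Downward they included DDC, CBLN2, GLP1R, CAMK2N1, ITGB2 (-2.57 at 48 h), FRMPD2 (-1.61), NIPSNAP3A (-2.54) and NWD1 (-2.30). Of the genes with a GC value, 109 were early transient upward and 39 downward and 59 and 184 late, and after correction 36 and 27 and 163 and 141; of the upward groups, 14 and 35 genes were in both sets.

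Whether the libraries lay in the order of time was asked by counting genes that rose or fell at every step. In the true order 274 genes did so, 105 rising and 169 falling, and 9 of the 360 possible orders gave at least as many, an exact share of 0.0250. The highest other order, 3, 0, 24, 12, 48 and 6 h, gave 513. After GC correction 290 genes followed the true order, and 5 of the 360 orders gave at least as many. The highest other order was then 3, 0, 6, 12, 24 and 48 h, with 399. Leaving out the 12 h library, 568 genes were monotone and 6 of 60 orders gave as many (0.1), and leaving out the 6 h or the 24 h library 5 of 60 did (0.0833). With the 3 h or the 48 h library left out, 2 of 60 did (0.0333). Without the 0 h library the true order had the most, 854 genes against 797 in the next. The 0 h and 3 h libraries were close to each other, with 192 genes apart by 2-fold and a Pearson correlation of 0.985 across genes of log2(CPM + 1), and 24 h and 48 h were at 0.984, whereas 0 h and 24 h were at 0.906. Much of that distance lay between 3 h and 6 h, which were at 0.912 with 2661 genes apart. The change between these 2 libraries correlated with GC content at r = -0.769. The 6 h library was at 0.968 with 24 h and 0.962 with 48 h. With 12 h, which lacks most counts of the regions, it was at 0.933.

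7 further lists had medians at 24 h within the middle 95% of random lists matched on expression, so their members are described; housekeeping genes (median -0.38, percentile 8.69) were at 1.91 with GC content matched as well, in the lowest 2.5%. Immediate early genes went both ways, with 4 of 12 higher and 3 lower: KLF4 had 2.78, NR4A1 2.03, BTG2 -1.45 and MYC -2.58. Of 11 interferon response genes 4 fell and 0 rose, IFITM1 with -1.89 and MX1 with -1.37, while OAS3 (-1.26) and IFI6 (-1.002) stood at -0.93 and -0.60 after GC correction, and IFI6 was also short of 2-fold with median-of-ratios scaling. On the list of p53 targets and apoptosis 2 of 17 rose and 3 fell; PMAIP1 had 1.89, TNFRSF10B 1.22, BBC3 -1.88 and BAX -1.30, with -0.76 for BAX after correction. Among 11 genes of DNA methylation and TET enzymes, IDH1 rose (1.39), and DNMT3B and UHRF1 had -0.87 and -0.85. Splicing and paraspeckle genes had 0 of 17 higher and 0 lower at 24 h, with SF3B1 at 0.87 and NONO at -0.67, and 1 higher and 2 lower at 48 h: SF3B1 (1.03), U2AF2 (-1.23) and HNRNPA1 (-1.65), with 0 higher and 4 lower after correction, 1 of these among the 2. Of single genes named by the fixed rule, the transcription factor gene GATA2 had -1.62, NRIP1 1.82, GRHL2 1.48 and ETV1 1.09, which was 0.38 after correction. Of 19 oxidative phosphorylation genes 0 rose and 0 fell, NDUFB3 being at 0.58 and SDHA at -0.55. Among 12 housekeeping genes B2M, the light chain of class I histocompatibility molecules, rose (2.17, corrected 1.54), RPLP0 fell at 48 h (-1.04, corrected -0.72, short of 2-fold), and GUSB, YWHAZ and PGK1 had -0.81, 0.77 and -0.68.

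Markers of other cell types and states were mostly under the count minimum. On the fibroblast list 3 of 10 genes were measured: fibronectin FN1, also made by epithelial cells, fell from 1313 to 219 CPM, COL3A1 went from 4.32 to 0.729 CPM and COL1A1 from 62.8 to 31.2 CPM. Of 10 leukocyte markers 3 were measured, and the actin-bundling LCP1 rose from 44.5 to 184 CPM, while CD68 and CSF1R were at 14.1 and 2.09 CPM at 24 h. Of 9 basal epithelial markers 2 were measured, ITGB4 with -2.00 and LAMA3 with 0.73. Of 13 neuroendocrine markers 4 were measured: SYT4 at 912 and 1868 CPM (1.03, corrected 0.36), ENO2 with -0.66, SYP with 0.26 and DLL3 with -1.22, corrected -0.50. Of 19 prostate long non-coding RNAs 1 was found in the deposited table and measured. The others had no line there under a matched name, so nothing can be said of their level. No value is given for the 1 measured because reads from the opposite strand cannot be told apart. Per-list medians were not computed for these lists, which had fewer than 5 measured members.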

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

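The differences in this part were picked out because a group of genes moved one way at 1 time and the other way at another; with 1 library per time, the difference between times was not tested. Mitosis genes lay above 0 h at 3 h, with a median log2 change of 0.53, and below it at 24 h, with -1.12. Genes of DNA replication and G1/S had a median of 0.42 at 3 h and -0.56 at 24 h. PLK1 was at 41.7, 72.1 and 9.03 CPM at 0, 3 and 24 h, CDC20 at 42.5, 68.9 and 9.91 CPM, and MCM2 at 107, 156 and 46.2 CPM.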

How the results depend on the processing

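The GC correction, the settings without chromosome regions or libraries, the 3 h reference, the deposited denominator, thinning and GC-matched random lists were chosen after the data were seen; the other settings were planned. Counts of genes stayed within 1.5 times in 16 of 16 cases with upper-quartile scaling, 16 of 16 without a count minimum, 10 of 10 with the deposited denominator and 10 of 10 after thinning. GC correction, which also leaves out the genes without a GC value, moved 14 of 18 counts by more: 48 genes were lower at 3 h, 423 higher and 174 lower at 6 h, 442 higher at 12 h, 790 and 734 at 24 h and 797 and 537 at 48 h, with 328 sustained genes up and 209 down, 36 early transient up and 27 down, 163 late up and 5 orders with as many monotone genes. On the same genes without correction 1165 were higher at 24 h and 39 early transient down, within 1.5 times. With both the correction and the regions left out, 15 of 16 moved: 48 were lower at 3 h, 395 and 163 changed at 6 h, 442 and 313 at 12 h, 739 and 699 at 24 h, 741 and 505 at 48 h, with 328 and 187 sustained, 33 and 25 early transient and 153 and 132 late genes. Leaving out the regions without the correction, and with them the genes of unknown chromosome, gave 427 lower at 12 h and 1 gene of the 12 h library apart from the others, because the genes removed include those lost there. Against the 3 h library, 167 were lower at 6 h, 2025 higher at 12 h, 1876 higher at 24 h, 1462 sustained up and 198 down. Without the 12 h library, 685 genes were sustained down and 568 monotone, fewer libraries being required. A mean of at least 100 counts, which tests fewer genes, gave 857 lower at 24 h, 73 early transient up, 217 sustained down, 132 late down, a median of -0.74 for mitosis genes at 48 h, and 9 and 7 genes apart in the 6 h and 24 h libraries. Median-of-ratios scaling gave 75 and 67 early transient, 105 and 130 late genes and 9 apart at 6 h. A pseudocount of 0.5 left 69 and 35 genes apart at 3 and 24 h. A pseudocount of 2 left 23, 7 and 6 apart at 3, 6 and 24 h, with 57 genes lower at 3 h and 26 early transient down. By Spearman correlation 1385 genes followed the time order, a looser demand. The mean in place of the median reversed the immediate early genes at 3 h to -0.0893. Except where the construction is named, the cause was not tested. Of named values past 2-fold, 188 of 191 stayed so with the median of ratios and 169 of 181 after GC correction. With a pseudocount of 0.5 it was 191 of 191, which was certain beforehand, because a smaller pseudocount only enlarges a change. A pseudocount of 2 was not run for the named genes. Most named genes were chosen by the size of their change, so these shares say little of other genes. Among all genes higher at 6, 24 and 48 h with a GC value, 21.2, 50.3 and 37.3% stayed past 2-fold after GC correction. Of 90 list medians 38 were called, 36 of them also with GC-matched random lists, which called 8 more: mitosis and splicing genes at 48 h, DNA replication at 6 and 12 h, amino acid transport and histones at 6 h, secretion at 3 h and housekeeping genes at 24 h. Among list medians not called, the mean had the other sign for mitosis and housekeeping genes at 12 h, immediate early genes at 12, 24 and 48 h, interferon response at 6 h and DNA methylation at 6, 24 and 48 h, and GC correction turned the sign of medians of fatty acid synthesis, mitosis, immediate early genes, p53 targets, DNA methylation and splicing at some times, none of them called. Summing a gene's lines against its highest line was not run, since it applied to normalized values. No paired analysis was possible because each group had 1 library. Depth limits what can be said of genes under 20 counts on average, which were left out.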

Other observations

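Tests of the loss at 12 h and of GC content, and the GC test of the hypoxia list, were chosen after the results were seen; the genes of the next 2 paragraphs were also picked after their values were seen. The genes named first act in protein glycosylation or translocation and were not tested as a group. UAP1, which makes the sugar donor for N-acetylglucosamine, went from 143 to 601 CPM at 24 h (log2 change 2.06, GC-corrected 1.88), PGM3 of the same pathway had 2.81 (corrected 2.17) and GFPT1, its first enzyme, 2.003 (corrected 1.30). The sialyltransferase ST6GALNAC1 went from 9.18 to 74.2 CPM at 48 h and EDEM3, which trims misfolded glycoproteins, from 24.2 to 396 CPM. SSR1, SSR3 and TRAM1, which help proteins into the endoplasmic reticulum, had 1.84, 1.90 and 2.06 at 24 h, with 1.33, 1.34 and 1.246 after correction, and SRP19 and the signal peptidase subunit SEC11C had 2.12 and 1.47.

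BAMBI, a decoy receptor of the TGF-beta family, went from 127 to 28.7 CPM at 24 h, the inhibitor SMAD7 from 17.0 to 3.93 CPM and vimentin VIM from 34.1 to 7.24 CPM. TIPARP, a target of the aryl hydrocarbon receptor like CYP1A1, went from 5.92 to 18.99 CPM at 3 h and 52.4 CPM at 6 h. Among the most abundant genes, HFM1, known as a meiotic helicase, stood at 11232, 17203 and 7647 CPM at 0, 6 and 24 h, and the phosphodiesterase PDE3A at 5965, 10031 and 4548 CPM. Where the reads counted for HFM1 and PDE3A came from was not examined, so these values need not be the levels of their messenger RNA.

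In the 12 h library, genes of chromosome 4 and distal chromosome 15 kept a median of 9.83% of the level around them in time, against 105% elsewhere. The total count was 1.03 times that of the 0 h library, which argues against low depth. Single-exon genes of the regions kept 0.404% of their reads and genes with over 8 exons 12.3%. These shares are against a loss or silencing of the regions in the cells, which would lower both alike. Genes with 2 to 3 exons kept 2.69% and those with 4 to 8 exons 19.6%. The shares pool the counts of each group, so abundant genes weigh most, and how far single genes drive them was not examined. The share kept followed the exon junctions per kb in the regions (Spearman 0.572 across 533 genes) and not elsewhere (0.0279), so a candidate explanation is that reads inside exons of these regions were lost in processing while reads across junctions were kept. RPL9 and RPS3A, on chromosome 4, stayed at 733 and 519.8 CPM, from 712 and 534 CPM at 6 h, and reads placed on other copies of these genes were not examined.

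Many more genes were past 2-fold from 6 h on than at 3 h. A GC-dependent difference between the libraries may account for most of the genes higher at 6 h, of which 21.2% (361 of 1701) stayed past 2-fold after correction. The GC trend that the correction removes does not account for all of the change, since 1524 genes were changed at 24 h after correction against 153 at 3 h. The correction takes away only that trend, so other technical differences between the libraries are not excluded by these counts. Greater depth is argued against by 2545 changed genes at 24 h against 188 at 3 h after thinning to the smallest library. Whether DHT itself acts on GC-poor transcripts or the libraries differ technically cannot be told apart, because each library from 6 h on had DHT. At 3 h the correlation across genes with GC content was 0.231, the opposite sign, but the trend was not a straight line. Its median log2 change rose from -0.34 at 37.4% GC to 0.04 at 54.5% and fell to -0.06 at 64.6%.

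Several genes known to be induced by low oxygen, such as PFKFB4 and PLOD2, were among the largest decreases at 3 h, and a list of 25 other hypoxia-induced genes was then written down before its values were seen. All 22 measured members lay below 0 h at 3 h, with a median of -0.47 at percentile 0 of random lists. This is in favour of a lower activity of the hypoxia response at 3 h than at 0 h, as a hypothesis. A raised level in the single 0 h library would give the same and cannot be told apart. Of the members 3 fell by 2-fold, PFKFB3 (-1.25), PDK1 (-1.05) and ZNF395 (-1.03). PFKFB3 and ZNF395, at 57.1 and 125 CPM at 0 h, stayed at 20.6 to 34.9 and 58.1 to 81.3 CPM at all later times. PDK1 was at 43.8 CPM at 0 h and back at 43.0 CPM at 6 h. The GC-corrected median of the list at 3 h was -0.37 with a spread of 0.0900, which argues against the GC trend as the cause of the fall. Spread here is a standard error of the median that takes the genes as independent, and it covers no difference between libraries. At 6, 12, 24 and 48 h the median was -0.15, 0.12, -0.13 and 0.28, at percentiles 12.4, 65.9, 33.7 and 93.1. The GC-corrected median was -0.44 at 6 h (spread 0.191), -0.28 at 12 h, 0.03 at 24 h and 0.19 at 48 h, so when the fall ended is left open. DHT and the handling of the cells, such as fresh medium, cannot be told apart, because no library treated without DHT for 3 h was used here.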
